A study of Mus musculus with 5 samples.

How the data were processed

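Gene expression was measured by RNA sequencing in 5 libraries of neutrophils sorted from mouse blood on the surface marker Ly6G after lysis of red cells. The mice were males of 7 to 10 weeks, and blood was taken at Zeitgeber time 13, or 20 h on the wall clock. Per the labels' protocols, polyadenylated RNA was amplified with a kit made for very small inputs and then built into Illumina libraries. The labels give 2 genotypes. In 2 libraries, numbered 2 and 3, Bmal1 (gene symbol Arntl) was floxed and crossed to a Cre driven by the Mrp8 promoter, which is active in neutrophils. In the other 3 libraries, numbered 1, 2 and 3, Cxcr4 was floxed and crossed to the same Cre. No unfloxed control was analysed here, so a difference between the groups cannot be assigned to either genotype. The labels name separate samples and do not say that each came from a separate animal, so p-values measure the spread between these samples, which may be partly technical.

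The values used are the normalised read counts the authors deposited, a non-negative signal per gene in a table of 19127 genes. The submitters' processing notes name CASAVA 1.8.2, cutadapt, RSEM 1.2.3 and the mouse genome build GRCm38, with no role or order. The normalisation method, the annotation, the strand setting and any filter on genes are not given in the sources used here. The totals of the deposited columns ran from 768169 to 1065836, so the values are not CPM of the listed genes. Within each library 100% of values were whole multiples of the smallest positive value, within 0.01 of a read, and whole reads were recovered by dividing by it. These recovered reads summed to 2869625 and 4058914 in libraries 2 and 3 labelled Bmal1-deficient, and to 356872, 4646391 and 9101826 in libraries 1, 2 and 3 labelled Cxcr4-deficient. The value of 3 reads, taken as the detection floor, was 6.46 in the shallowest library and between 0.351 and 0.902 in the other 4. Reads without molecular identifiers are not independent molecules, so floors cover counting error only.

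Gene identifiers were matched to GENCODE symbols, with 18847 of 19127 matched, and gene positions were taken from GENCODE M21 on GRCm38. In all 5 libraries 990 genes were at 0. The main test was limma 3.58.1 (R 4.3.3) on log2(value + 1), with an intensity-dependent variance prior, for the 14632 genes with a mean CPM of at least 1, where columns were rescaled to CPM for this filter only. The coefficient was the group labelled Bmal1-deficient minus the group labelled Cxcr4-deficient, tests were two-sided, and the threshold was a Benjamini-Hochberg adjusted p of 0.05. Fold differences are on this log2 scale with a pseudocount of 1 and understate differences of low genes. The residual degrees of freedom were 3 and the prior added 5.36. The test had been fixed for normalised values. Because whole reads could be recovered, the quasi-likelihood test of edgeR 4.0.16 was run on them as planned for that case, and DESeq2 1.42.0 was added after the data were seen.

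Gene lists were tested with camera (limma) at a preset inter-gene correlation of 0.01, again with the estimated correlation, and with fry, each adjusted over the lists. Of the 35 lists fixed, 33 had at least 3 tested members. They cover the circadian clock, neutrophil ageing, granules, migration, inflammation, metabolism, translation and markers of other blood cells. Another 8 marker lists (endothelium of 3 kinds, hepatocytes, lung epithelium, fibroblasts, Kupffer cells and core neutrophil genes) were written after a first look at the values and tested as a separate family. Genes that had prompted that look were left out of them. The lists for the liver sinusoidal and lung capillary endothelium share 1 gene each with the fixed lists, the pan-endothelial list shares 2 and the core neutrophil list shares 11 of 16.

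Genes were named by a fixed rule. The rule takes both targeted genes, then up to 12 genes per direction with an adjusted p under the threshold and no overlap between groups. If fewer pass, it takes the 6 lowest unadjusted p-values of each direction, named as not past the threshold. It adds up to 4 members per list with the smallest p, the clock genes and the members of both ageing lists. Members of lists that did not pass are named only for the clock and ageing lists, or where said to be chosen after their values were seen. Of the genes the rule takes, 2 are not reported here. The samples, the tests, the 35 lists, the naming rule and the alternatives were fixed before the data were examined, except where an alternative is said to have been added.

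The replicate numbers 2 and 3 occur in both groups, and no label ties them to a litter, day or batch, so the samples were not paired in the main test. Replicates were not duplicates. Within a group the chi-square per degree of freedom between the recovered reads of any pair of libraries was between 23.5 and 162. The alternatives were the pseudocount, the low-value filter, 3 other scalings, 2 other variance priors, array weights, the replicate number as a block, leaving out each library, the count model, an estimated correlation and fry. Added after the data were seen were DESeq2, 3 fits without pairs of libraries, and a covariate made of liver sinusoidal minus lung capillary endothelial genes.

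The gene test was checked on counts simulated for the same 14632 genes, library sizes and dispersions with 200 genes changed. With the dispersion seen among the 5 libraries, limma recovered 0% of the changed genes at 2-fold and at 4-fold, 1% at 8-fold and 41% at 16-fold. With a dispersion of 0.05 it recovered 0% at 2-fold, 84.5% at 4-fold and 98.5% at 8-fold. With the dispersion seen among the 5 libraries, edgeR recovered 0%, 1.5%, 37% and 69.5% at 2-fold, 4-fold, 8-fold and 16-fold. There it made 3, 5, 27 and 28 false calls, against 0, 1, 0 and 2 by limma. DESeq2 was not checked in this way. At an unadjusted camera p under 0.05, the list test recovered a shift of 1 on the log2 scale in 20 of 20 simulated lists. The lists held 20 genes, and an unchanged list was called in 2 of 20. Genes were simulated independently of each other. This check therefore does not cover false calls at the preset correlation where the genes of a list vary together. Splits of 5 samples into 2 and 3 number 10, so an exact permutation test of a single value cannot go below 0.1.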

Results

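The series profiled neutrophils sorted from mouse blood in which 1 of 2 genes had been floxed for deletion in the myeloid lineage. Bmal1 (Arntl) encodes a core activator of the circadian clock, and Cxcr4 encodes the receptor for the chemokine CXCL12 that retains neutrophils in bone marrow. Both have been linked to the daily ageing of neutrophils in blood, which is the question that this pair of genotypes addresses. There were 2 libraries labelled Bmal1-deficient (numbers 2 and 3) and 3 labelled Cxcr4-deficient (numbers 1, 2 and 3), all taken at Zeitgeber time 13. Depth ran from 356872 reads in Cxcr4-labelled library 1 to 9101826 in Cxcr4-labelled library 3. The 10 most abundant genes held between 14.9% and 21.8% of reads. Values are normalised read counts, and differences are Bmal1-labelled minus Cxcr4-labelled on the log2(value + 1) scale with a standard error (SE) from limma.

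The targeted genes were compared first, in every library. Cxcr4 (chromosome 1, 128588199 to 128592293, minus strand of GRCm38, protein-coding) had values of 398.6 and 127.8 in Bmal1-labelled libraries 2 and 3. It had 15.1, 72.2 and 4.80 in Cxcr4-labelled libraries 1, 2 and 3, with no overlap between the groups. The difference was 3.58 (SE 1.02), with an unadjusted p of 0.00735 and an adjusted p of 0.9999 by limma. Neutrophil content differed between libraries and was not adjusted for. Core neutrophil genes made up 0.0455% of the column in Cxcr4-labelled library 3, which had the lowest Cxcr4 value. They made up 0.586% in Cxcr4-labelled library 2 and 1.38% and 0.925% in Bmal1-labelled libraries 2 and 3. Cxcr4-labelled library 1 had the largest share, 1.93%, with a low Cxcr4 value. Arntl (chromosome 7, 113207465 to 113314126, plus strand, protein-coding) did not follow the labels. It stood at 4.81 and 27.6 in Bmal1-labelled libraries 2 and 3, against 15.1, 1.90 and 1.05 in Cxcr4-labelled libraries 1, 2 and 3. The difference was 1.49 (SE 1.24), within the spread between libraries (limma unadjusted p 0.262). These values cover whole genes, and reads from exons outside a floxed segment, or from cells without the Cre, can remain. The groups are therefore named by their labels throughout.

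No gene passed the adjusted threshold between the groups. limma called 0 of 14632 genes, with 612 at an unadjusted p under 0.05 (539 higher and 73 lower in Bmal1-labelled libraries) where chance alone would give about 731.6. edgeR called 0, with 524 at an unadjusted p under 0.05 (357 higher and 167 lower). DESeq2, added after the data were seen, called 13, of which 5 were higher and 8 lower, with 682 at an unadjusted p under 0.05 (332 higher and 350 lower), so the split of directions differed between tools. The lowest adjusted p by DESeq2, 3.16e-07, was that of Gm13192, with 140 reads in Cxcr4-labelled library 2 and 0 in every other library. A call by DESeq2 can thus rest on 1 library. The groups did not overlap for 2757 genes, or 18.8% of those tested, and chance gives 20%.

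The genes with the lowest unadjusted p are given by value, none being past the threshold with limma or edgeR. Siglecf, which encodes a sialic acid-binding receptor best known on eosinophils (chromosome 7, 43351341 to 43359531, protein-coding), had 80 and 73 reads in the Bmal1-labelled libraries and 0 in all 3 Cxcr4-labelled libraries. Against a floor of 3 reads per library it was at least 8.15-fold higher, and DESeq2 called it with an adjusted p of 0.00521. Rpl17, a ribosomal protein gene, had 48 and 98 reads against 0, at least 7.34-fold higher, and was called by DESeq2 with an adjusted p of 0.0104. Ribosomal protein genes have near-identical processed copies among which reads can be split, so this value is uncertain. Slc24a1 (12.4 ± 2.91, SD, n = 2, against 0.187 ± 0.177, SD, n = 3), Ugt1a6a, Bri3bp and Fhl3 completed the higher set. Between 0 and 4 reads per Cxcr4-labelled library were found for these 4 genes. All 4 were at 0 in Cxcr4-labelled library 1, where 3 reads equal 6.46 normalised counts. Their values in Bmal1-labelled library 3, from 7.18 (Fhl3) to 10.3 (Slc24a1), are little above that floor, so this 0 says little.

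On the lower side were 2 clock genes. Tef, a D-box transcription factor of the clock output (chromosome 15, 81802421 to 81826863), averaged 5.96 ± 3.04 (SD, n = 2) in Bmal1-labelled and 107.8 ± 86.7 (SD, n = 3) in Cxcr4-labelled libraries. Its difference was -3.52 (SE 0.96), and DESeq2 called it with an adjusted p of 0.0142. Per2, a clock repressor (chromosome 1, 91415982 to 91459324), averaged 26.1 ± 13.7 (SD, n = 2) against 101.6 ± 30.9 (SD, n = 3), a difference of -1.98 (SE 0.56). Galnt15 was at 9.19 ± 1.89 (SD, n = 2) against 52.6 ± 16.2 (SD, n = 3). Rad9b (5 and 4 reads in Bmal1-labelled libraries 2 and 3, and 9, 118 and 138 in Cxcr4-labelled libraries 1, 2 and 3), Rgs5 (17.8 against 85.6), a pericyte marker, and Snupn (1.31 against 17.0) completed this set. All 6 had no overlap between groups. DESeq2 also called Rad9b at an adjusted p of 0.0244.

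The clock output genes were lower as a list in the Bmal1-labelled libraries. Of the 15 members of the negative limb and D-box output, which BMAL1 with CLOCK activates through E-boxes or which lie downstream, 13 had negative differences and 2 positive ones, with a median of -1.39. Camera gave an adjusted p of 1.77e-05 over 33 lists at the preset correlation, and an adjusted p of 0.747 with an estimated correlation. The list summed to 404.1 and 220.4 in Bmal1-labelled libraries 2 and 3. It summed to 301.4, 930.2 and 1149 in Cxcr4-labelled libraries 1, 2 and 3, so library 1 lay between the Bmal1-labelled libraries. No member passed over all genes or when adjusted over the list alone, where Tef and Per2 each had an adjusted p of 0.054. Nr1d1 (19.7 ± 7.93 against 54.5 ± 24.1) and Per3 (6.82 ± 0.133 against 35.1 ± 22.8), with SD over 2 and 3 libraries, also had no overlap. Nr1d2 averaged 31.3 against 156.0, and Bhlhe40 36.9 against 93.5, and both overlapped between the groups. Dbp (2.92 against 57.6), Hlf (2.41 and 0 in Bmal1-labelled libraries 2 and 3, mean 13.7 in the other group), Bhlhe41 (0.713 against 16.6) and Cry2 (6.37 against 21.2) had lower group means and overlapped. Dbp had 0 reads in Cxcr4-labelled library 1, where 3 reads equal 6.46 normalised counts. Per1, Usp2, Ciart, Wee1 and Cry1 differed by less than their SE. Pan-endothelial genes were lower in the same libraries, with a median of -0.51. The list stayed under the threshold in each of the 5 fits without 1 library, but its median shrank to -0.52 without Cxcr4-labelled library 3 (adjusted p 0.00461). Without both libraries numbered 3 it was -0.26 and did not pass (adjusted p 0.179); wherever a single Bmal1-labelled library is left, here and in the fits named below, the spread comes from the Cxcr4-labelled group alone and that library is assumed to vary like it.

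**Figure D1:**
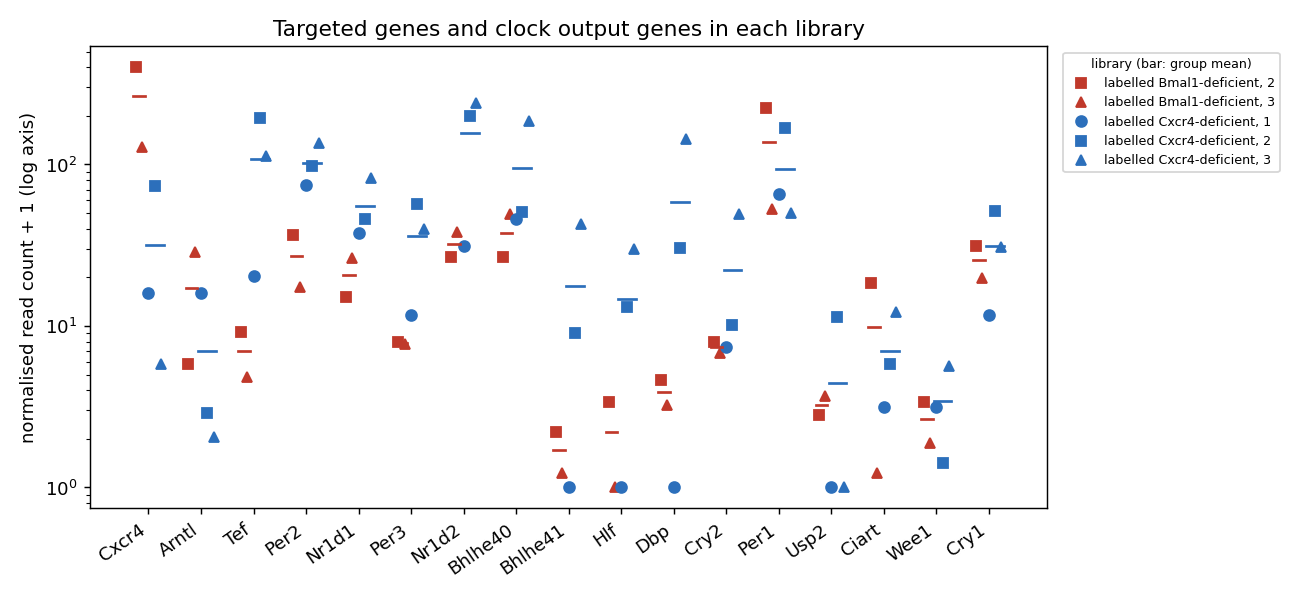
Normalised read count plus 1 on a log axis for Cxcr4, Arntl and the 15 clock output genes, with 1 point per library (red, labelled Bmal1-deficient; blue, labelled Cxcr4-deficient; marker shape, library number) and a bar at each group mean. Tef, Per2, Nr1d1 and Per3 show no overlap between groups, whereas Arntl overlaps.

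The positive limb and RORE-driven clock genes did not pass (6 tested members, adjusted p 0.669), and their median (0.13) and mean (-0.0047) differed in sign. Rora, a nuclear receptor that activates through ROR elements, averaged 15.8 ± 1.48 (SD, n = 2) against 65.9 ± 36.9 (SD, n = 3), without overlap. Nfil3 averaged 15.8 against 8.25 and Csnk1d 214.0 against 161.0. Csnk1e and Clock differed by less than their SE.

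Neither list of neutrophil ageing passed. The 12 genes described as higher on aged neutrophils had a median of 1.13 and an adjusted p of 0.0553. The 10 described as higher on fresh neutrophils had a median of 0.91 and an adjusted p of 0.0613, and a median of -0.17 with edgeR. Both gave an adjusted p of 0.747 with an estimated correlation. The aged list passed without Cxcr4-labelled library 2 (median 1.40, adjusted p 0.010) and had a median of 0.43 without Cxcr4-labelled library 3 (adjusted p 0.726) and -0.12 without Cxcr4-labelled libraries 1 and 3. The fresh list passed without Cxcr4-labelled library 1 (median 2.23, adjusted p 0.00263), and its median was 0.051 without Cxcr4-labelled library 3 (adjusted p 0.849). On the aged list, Fgl2 averaged 916.4 ± 489.6 (SD, n = 2) against 144.3 ± 125.2 (SD, n = 3), Itgax 121.4 against 19.7 and Itga4 800.9 against 188.0, each without overlap. Mmp9 (1114.9 against 383.2), Il1b (1812 against 1140) and Itgam (342.0 against 248.2) overlapped, and Tlr4 (97.2 against 56.1) did not. Icam1, Fas, Cxcl2 and Cd14 had lower means, and Tnf differed by less than its SE. On the fresh list, Cxcr2, the receptor for CXCL2, averaged 909.1 ± 200.2 (SD, n = 2) against 266.6 ± 213.5 (SD, n = 3). Selplg averaged 421.8 against 172.2 and Padi4 78.4 against 60.9. Cd47, Cd24a, Mmp8, Retnlg, Ly6g and Anxa1 differed by less than their SE. Core neutrophil genes moved with these lists, and Cxcr4-labelled library 3 was the lowest for each member named with no overlap.

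Migration genes were higher as lists. Chemoattractant receptors had 13 of 16 members with positive differences (median 1.16, camera adjusted p 0.0154), led by Ccr1 (419.5 ± 153.4, SD, n = 2, against 77.0 ± 65.6, SD, n = 3). Ptafr, for platelet-activating factor, averaged 226.3 against 80.1, and C5ar1, for the complement fragment C5a, 460.9 against 184.9. Adhesion and rolling genes had 16 of 23 positive (median 0.59, adjusted p 0.0195), with Jaml at 291.6 against 77.4 beside Itgax and Itga4. Cytoskeleton and motility genes had 24 of 27 positive (median 0.75, adjusted p 0.000365), with Rac2 at 384.7 against 167.4 and Coro1a at 477.4 against 198.9. Each of these lists had an adjusted p of 0.747 with an estimated correlation, and no member passed when adjusted over the list alone. Core neutrophil genes summed to 1.38% and 0.925% of the column in the Bmal1-labelled libraries, and to 1.93%, 0.586% and 0.0455% in Cxcr4-labelled libraries 1, 2 and 3. Adhesion genes summed to 0.843% in Cxcr4-labelled library 1, between Bmal1-labelled libraries 2 and 3 (1.05% and 0.727%). Cytoskeleton genes there summed to 2.71%, also between them (2.81% and 1.90%). Receptor sums did not overlap (0.319% and 0.201%, against 0.180%, 0.132% and 0.0105% in Cxcr4-labelled libraries 1, 2 and 3). All 3 calls ended without Bmal1-labelled library 2 (adjusted p 0.546, 0.830 and 0.379) and without Cxcr4-labelled library 3 (0.332, 0.355 and 0.169), and those of the receptors and of adhesion also without Bmal1-labelled library 3 (0.0571 and 0.0539). Without Cxcr4-labelled library 3 the medians were 0.66, 0.40 and 0.41, without Cxcr4-labelled library 1 those of receptors and cytoskeleton were 2.06 and 1.14, and that of adhesion was 1.68 without Bmal1-labelled library 3 and 1.10 without Cxcr4-labelled library 2. The adhesion call also ended with median-ratio scaling (0.0510), columns scaled to the same total (0.0599), no filter on low values (0.196) and no intensity trend (0.0860).

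Innate sensing and response genes were also higher as lists. Interferon-stimulated genes had 30 of 39 members with positive differences (median 0.91, adjusted p 0.00015), and 20 members had no overlap. Oasl2 averaged 269.6 ± 36.6 (SD, n = 2) against 77.3 ± 62.0 (SD, n = 3), and Oas3 206.5 against 62.5, both encoding proteins of the oligoadenylate synthetase family. Oasl1 averaged 28.6 against 4.48. Pattern recognition and phagocytic receptors had 22 of 28 positive (median 1.63, adjusted p 0.00015), including Fcgr4 (72.8 ± 3.73, SD, n = 2, against 19.6 ± 20.3, SD, n = 3), Clec7a (455.9 against 106.3) and Tlr8 (40.0 against 8.70). Immediate early and stress genes had 23 of 31 positive (median 0.69, adjusted p 0.000723). Zfp36, which encodes an mRNA-destabilising protein, averaged 1174 ± 515.0 (SD, n = 2) against 332.4 ± 20.9 (SD, n = 3), Junb 804.7 against 209.4, Btg1 655.7 against 141.9 and Fos 1675 against 496.8, all without overlap. With an estimated correlation each list had an adjusted p of 0.747. The core neutrophil list moved the same way, with a median of 1.44. Pattern recognition genes summed to 0.475% and 0.473% of the column in Cxcr4-labelled libraries 1 and 2. Both sums lay between those of Bmal1-labelled libraries 2 and 3 (0.567% and 0.468%). Sums of the interferon and immediate early lists did not overlap between groups. The interferon list stayed under the threshold in each fit without 1 library, 2 of which leave a single Bmal1-labelled library. The other 2 ended without Bmal1-labelled library 2 (0.0947 and 0.390) and without Cxcr4-labelled library 3 (0.111 and 0.131). The median of pattern recognition was 0.71 without Cxcr4-labelled library 3, and that of immediate early genes 0.30 without Bmal1-labelled library 2.

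Respiratory and translation genes were lower as lists in the Bmal1-labelled libraries. Mitochondrially encoded genes had 10 of 11 members with negative differences (median -0.75, adjusted p 0.000764), with mt-Nd4l at 766.8 ± 135.5 (SD, n = 2) against 1677 ± 427.2 (SD, n = 3) and mt-Nd5 at 2113 against 4151. Nuclear-encoded oxidative phosphorylation genes had 36 of 52 negative (median -0.22, adjusted p 0.0154), with Cox6b1 at 24.9 against 68.3 and Uqcrb at 47.1 against 100.9. Translation factors and nucleolar genes had 15 of 23 negative (median -0.29, adjusted p 0.0169), with Eif3h at 48.3 against 102.2 and Eif3e at 37.6 against 74.1. Each list had an adjusted p of 0.747 with an estimated correlation, and pan-endothelial genes were lower in the same libraries. Oxidative phosphorylation genes summed to 0.217% of the column in Cxcr4-labelled library 1, between Bmal1-labelled libraries 2 and 3 (0.207% and 0.243%). Translation genes there summed to 0.598%, also between them (0.567% and 0.638%). Sums of mitochondrially encoded genes did not overlap (1.44% and 2.44%, against 2.69%, 2.84% and 3.52% in Cxcr4-labelled libraries 1, 2 and 3). All 3 calls ended without Bmal1-labelled library 2 (adjusted p 0.390, 0.177 and 0.274), and those of oxidative phosphorylation and translation also without Cxcr4-labelled library 3 (0.355 and 0.488) and with quantile normalisation (0.0849 and 0.0661), and that of translation with no intensity trend (0.0547). Without 1 library the medians ran from -1.29 to -0.43 for mitochondrially encoded genes (without Bmal1-labelled libraries 3 and 2), from -0.52 to -0.016 for oxidative phosphorylation and from -0.53 to -0.052 for translation (both without Cxcr4-labelled libraries 1 and 3 in turn).

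Markers of other blood cells were read beside these lists. Erythroid genes were higher as a list (9 of 10 positive, median 2.76, adjusted p 0.000305, and 0.747 with an estimated correlation). They summed to 0.358% and 0.263% of the column in the Bmal1-labelled libraries and to 0.295%, 0.0154% and 0.0222% in Cxcr4-labelled libraries 1, 2 and 3. Hba-a2 (440.9 against 94.4) and Hbb-bs (1490 against 476.4) have close paralogs, so reads can be split among copies, while Alas2, of haem synthesis, averaged 63.3 against 13.3. The erythroid call ended without Bmal1-labelled library 2 (adjusted p 0.163) and without Cxcr4-labelled library 3 (0.0621). B cell, T cell, monocyte and macrophage, platelet, eosinophil and dendritic cell lists did not pass. Siglecf was the 1 member of any of the 33 lists that passed when adjusted over its list alone (3 tested eosinophil genes, adjusted p 0.00298). The other 2, Ccr3 and Ear2, overlapped between the groups. The NK cell list and the list for basophils and mast cells had fewer than 3 tested members and were not tested.

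In all, 11 of 33 lists passed camera at the preset correlation, 7 higher and 4 lower, and 0 passed with an estimated correlation or by fry. At an unadjusted p under 0.05 there was 1 list with the estimated correlation (interferon-stimulated, 0.0275) and 2 by fry (interferon-stimulated, 0.0177, and chemokines, 0.0264). Without Cxcr4-labelled library 1 the count of lists was 17, without Bmal1-labelled library 2 it was 3 and without Cxcr4-labelled library 3 it was 5. The lists of granule contents, the NADPH oxidase, chemokines, inflammatory cytokines, cell cycle, apoptosis, glycolysis, ribosomal proteins, lysosomes, MHC class I and the sex check did not pass. Of the 23 alternatives, ribosomal proteins passed in 8, glycolysis in 7, the NADPH oxidase in 3 and specific granules in 1. Gelatinase granules, inflammatory cytokines and cell cycle passed in 2 each, and the others in none.

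Endothelial transcripts were abundant in all 5 libraries, by lists written after the first look at the values. Pan-endothelial genes, such as Flt1, Erg and Egfl7, summed to 0.538% and 0.563% of the column in the Bmal1-labelled libraries and to 0.544%, 0.941% and 0.895% in Cxcr4-labelled libraries 1, 2 and 3. As a list they were lower in the Bmal1-labelled libraries (median -0.51, adjusted p 0.000411 over 8 lists, and 0.883 with an estimated correlation). Liver sinusoidal endothelial genes summed to 1.39% and 2.20% in the libraries numbered 3, to 0.0923% and 0.153% in those numbered 2 and to 0.487% in library 1. They did not pass (median -0.52, adjusted p 0.187), with the sum lower in the Bmal1-labelled library of each shared number. They passed as lower without Bmal1-labelled library 3 (median -2.72, adjusted p 0.000207) or Cxcr4-labelled library 2 (median -1.85, adjusted p 0.00181), and the median was 1.73 without Bmal1-labelled library 2 and 0.82 without Cxcr4-labelled library 3. Lung capillary endothelial genes followed the opposite order, with 0.896% and 1.68% in the libraries numbered 2, 0.207% and 0.331% in those numbered 3 and 0.541% in library 1. This list was lower in the Bmal1-labelled libraries (median -0.62, adjusted p 0.00255, and 0.883 with an estimated correlation), a call lost without Bmal1-labelled library 3 (median 0.56, adjusted p 0.632) or Cxcr4-labelled library 2 (median 0.088, adjusted p 0.674). Its median was -2.68 without Bmal1-labelled library 2 and -2.02 without Cxcr4-labelled library 3. The pan-endothelial call was also lost without Cxcr4-labelled library 2 (median -0.22, adjusted p 0.0519), and its median was -0.90 without Cxcr4-labelled library 1. Core neutrophil genes were higher in the Bmal1-labelled libraries (median 1.44, adjusted p 0.000168, and 0.883 with an estimated correlation), with Csf3r at 1839 ± 708.0 (SD, n = 2) against 460.9 ± 430.4 (SD, n = 3). That call was lost without Bmal1-labelled library 2 (0.0738) or Cxcr4-labelled library 3 (median 0.33, adjusted p 0.293), and the median was 2.23 without Cxcr4-labelled library 1. Hepatocyte, lung epithelial, fibroblast and Kupffer cell lists did not pass.

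**Figure D2:**
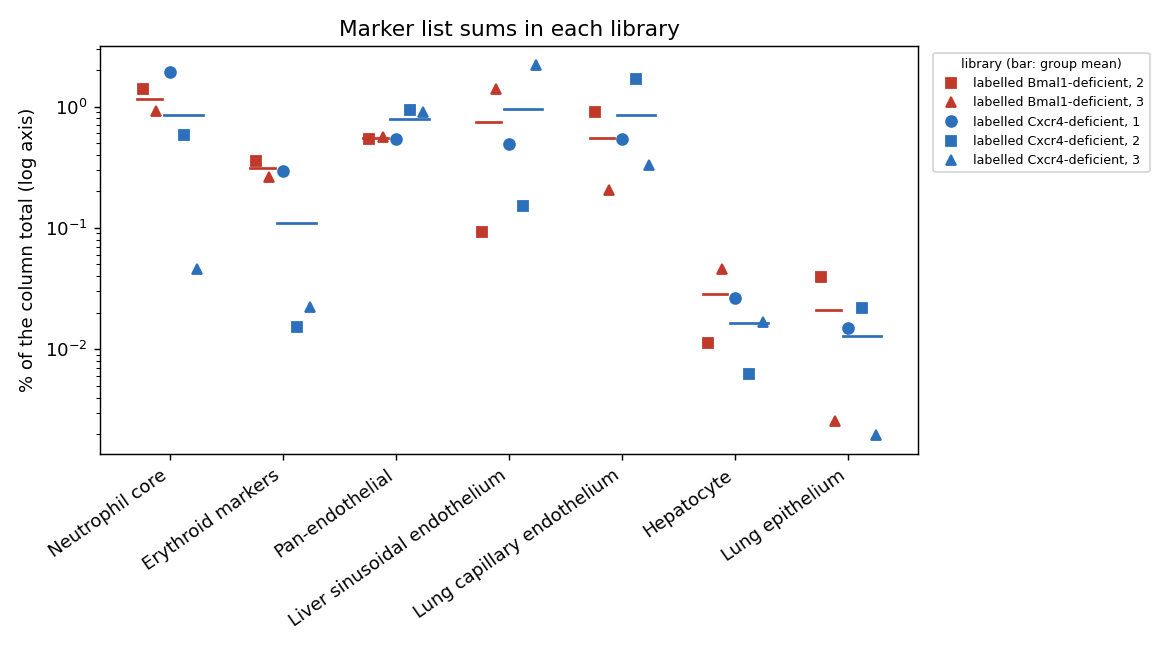
Sum of each marker list as a percent of the column total, on a log axis, with 1 point per library (red, labelled Bmal1-deficient; blue, labelled Cxcr4-deficient; marker shape, library number) and a bar at each group mean. Liver sinusoidal genes are highest in the libraries numbered 3 (1.39% and 2.20%), lung capillary genes in those numbered 2 (0.896% and 1.68%), and core neutrophil genes lowest in Cxcr4-labelled library 3 (0.0455%).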

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

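The fits without pairs of libraries, the endothelial covariate and DESeq2 were chosen after the data were seen. The count of genes past the threshold was 0 under 21 of 22 alternatives and 13 with DESeq2; the cause was not tested. Quantile normalisation moved the median difference of all genes from 0.107 to -0.0435. The count of lists, 11, stayed within 1.5 times under 14 of 23 alternatives. It was 17 with the replicate block, 0 with the estimated correlation, 0 by fry, 0 without both libraries numbered 3, 1 without both numbered 2 and 6 without Cxcr4-labelled libraries 1 and 3, and it ranged from 3 to 17 in the fits without 1 library (3 without Bmal1-labelled library 2, 5 without Cxcr4-labelled library 3 and 17 without Cxcr4-labelled library 1). These smaller fits hold fewer samples, and where 1 Bmal1-labelled library is left it is assumed to vary like the other group; otherwise the cause was not tested. The numbers 2 and 3 are shared, and the differences of library 2 minus library 3 correlated across genes between groups (r = 0.385). The block compares the groups within these 2 numbers. Cxcr4-labelled library 1, alone in its number, adds nothing to the difference. Medians under the block therefore equal those without that library (0.00536 over all genes in both), and the 2 are not separate alternatives. The block also leaves fewer residual degrees of freedom than the 3 of the main fit. No label says what the numbers mark, so the block was not the main test. The clock output list was called in the same direction under 20 of 23 alternatives and the interferon list under 19. One of these, a robust variance prior, does not enter the list test and leaves every list as in the main fit. Neither list passed with the estimated correlation or by fry. Each ageing list passed under 6 of 23, with an adjusted p of 0.0113 (aged) and 5.18e-05 (fresh) under the block, and from 0.00179 to 0.926 (aged) and 5.18e-05 to 0.851 (fresh) over all alternatives. The fresh list had a median of -0.17 with edgeR, and the aged list -0.12 without Cxcr4-labelled libraries 1 and 3. The adhesion call was kept under 11 of 23 alternatives, and that of translation under 14. With a pseudocount of 10, the medians fell from 2.76 to 1.30 for erythroid genes, from 1.16 to 0.38 for chemoattractant receptors and from 1.63 to 0.81 for pattern recognition. These lists still passed there. The 27 lists that did not pass had 617 values under alternatives, of which 48 passed in the same direction, 0 passed in the other direction and 74 had the other direction of the test without passing; lists with no call were counted as turned only where they passed the other way, a rule set after these values were seen. The lung capillary list turned without Bmal1-labelled library 3 (median 0.56, and 0.088 without Cxcr4-labelled library 2). Its median ran from -2.68 to 0.56 in the fits without 1 library and down to -3.09 without Cxcr4-labelled libraries 1 and 3. The liver sinusoidal list passed under the block (median -0.53, adjusted p 0.00128) and with the endothelial covariate (2.67e-05), which is built partly from its own genes.

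Differences of named genes, none past the threshold with limma, turned sign as follows, and the cause was not tested. Without both libraries numbered 3, Arntl was -0.23, Usp2 -0.26, Ciart 2.10, Wee1 0.69, Cry1 0.34, Tnf -1.16, Retnlg -0.13 and Anxa1 -0.50. Without both numbered 2, Per1 was -0.11, Cry1 0.061, Csnk1e -0.14, Clock 0.43, Cxcl2 0.61, Cd14 0.34, Ly6g -0.38 and Anxa1 -0.24. Without Cxcr4-labelled libraries 1 and 3, Per1 was -0.62, Usp2 -1.82, Wee1 0.84, Il1b -0.66, Tnf -1.82 and Cd24a -0.45. With edgeR and DESeq2, in that order, Usp2 was -0.72 and -0.70, Ciart 0.52 and 0.55, Tnf -0.47 and -0.48, Mmp8 -0.43 and -0.53, Retnlg -0.62 and -0.71, Ly6g -0.81 and -1.01, and Anxa1 -0.66 and -0.74. A pseudocount of 10 gave Usp2 -0.050, Ciart 0.10, Tnf -0.012 and Ly6g -0.063. Usp2 was -0.066 with the block and Tnf -0.013 with quantile normalisation. Without 1 library, the ranges were -0.63 to 1.44 for Per1, -0.54 to 0.22 for Clock, -0.78 to 1.02 for Anxa1, -2.31 to 1.60 for Ciart, -0.74 to 0.26 for Wee1, -0.68 to 0.39 for Cry1, -0.42 to 1.47 for Tnf, -2.71 to 0.029 for Kitl, -0.066 to 1.69 for Usp2, -3.01 to 0.49 for Cxcl2, -2.31 to 0.90 for Cd14, -0.25 to 2.23 for Ly6g, -0.57 to 1.8 for Cd24a, -0.23 to 2.15 for Mmp8 and -0.37 to 2.23 for Retnlg. In Cxcr4-labelled library 1, with 356872 reads, 6340 of 19127 genes were at 0 and differences of genes below 6.46 normalised counts cannot be read.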

Other observations

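All tests in this part were chosen after the values they bear on had been seen, and the marker lists for endothelium, parenchyma and core neutrophil genes were written after a first look. Single genes given here outside the naming rule were likewise chosen after their values were seen.

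Cxcr4-labelled library 1 stood apart in secondary granule genes. Ngp had a normalised read count of 1229 there and between 6.28 and 25.6 in the other 4 libraries, Ltf 858.9 against 3.14 to 22.8, and Camp 282.0 against 0.448 to 3.01. Retnlg (921.3) and Lcn2 (1040) were highest there too. These genes are transcribed in the marrow during late maturation. DESeq2 called Ngp (adjusted p 0.0299) and Ltf (adjusted p 0.0244) as lower in the Bmal1-labelled libraries, and the specific granule list as a whole did not pass camera (median -0.38, adjusted p 0.173). Without Cxcr4-labelled library 3 that list passed as lower (median -1.47, camera adjusted p 0.000418). Without Cxcr4-labelled library 1 its median turned to 0.53. Beside Siglecf, Rpl17, Tef and Rad9b, DESeq2 called 7 more genes. Gm24447, Gm26541 and Gm16894 were higher in the Bmal1-labelled libraries, and Gm13192, Gm12482, Ppp1r2-ps2 and the gene ENSMUSG00000060214 were lower, with 0 reads in both of those libraries. Gm13192 had 140 reads in Cxcr4-labelled library 2 and 0 in the other 4.

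Xist, the X-inactivation transcript of female cells, had 304 reads in Bmal1-labelled library 3, 1 in Bmal1-labelled library 2, 1 in Cxcr4-labelled library 1 and 0 in Cxcr4-labelled libraries 2 and 3, although the labels give male donors. The Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty had reads in all 5 libraries, and Ddx3y had 251 in Bmal1-labelled library 3.

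The kind of endothelial RNA, liver or lung, followed the library number, although sorting on Ly6G should remove endothelial cells. Stab2, of liver sinusoids, had 4096 and 5907 in the libraries numbered 3 and 121.5 and 140.0 in those numbered 2, while Scn7a, of lung capillaries, had 53.8 and 45.8 against 1536 and 2822. Genotype is argued against for this balance alone, since the largest genotype gap in the liver-minus-lung index was 0.132 of the smallest gap between numbers, and so is whole liver or lung tissue, since parenchymal genes summed to at most 0.0441 of the endothelial sum in the 4 libraries numbered 2 or 3 (Alb at most 239.5). That 1 endothelial source per tissue was mixed into all libraries cannot be told apart from separate sources: 2 of 4 comparisons of gene ratios had ratios tighter than over 95% of 10000 matched random lists, but in another a share of 0.761 of the random lists was as tight, nor can genotype be told apart from other sources of the amount, the pan-endothelial percent of the column being lower in the Bmal1-labelled library in 0.833 of 6 comparisons between groups. Exchange with an outside sample, carry-over between sequencing indexes or a wrong label may each account for it and were not tested. In Cxcr4-labelled library 3 the endothelial genes Ptprb, Kdr and Stab2 ranked 6, 9 and 10 by abundance. The neutrophil genes S100a9 and Csf3r ranked 1363 and 4233 there. In Bmal1-labelled library 3, of the same number, Ptprb, Kdr, Stab2, S100a9 and Csf3r ranked 9, 14, 10, 23 and 37. In Bmal1-labelled library 2 these 5 genes ranked 33, 105, 1433, 12 and 16.

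Clock output genes were lower in the Bmal1-labelled libraries, also within each number (median -1.60 between the libraries numbered 2 and -2.67 between those numbered 3, against -1.01 and -0.72 for pan-endothelial genes). Cxcr4-labelled library 1 has no Bmal1-labelled library of its number. Its list sum, 301.4, lay between those of the Bmal1-labelled libraries (404.1 and 220.4). A lower amount of endothelial RNA cannot be told apart from a separate change of the clock genes. The mean difference of the clock list minus that of the pan-endothelial list was -0.723 (log2, permutation p 0.0167 over 31 genes, which are not independent), -1.18 without Bmal1-labelled library 2 (p 0.0006), -1.05 without Cxcr4-labelled library 1 (p 0.00971) and -0.68 without Cxcr4-labelled library 2 (p 0.0425), but -0.44 without Cxcr4-labelled library 3 (p 0.0913), -0.27 without Bmal1-labelled library 3 (p 0.477) and 0.021 without both (p 0.948). RNA taken at another time of day cannot be told apart from loss of BMAL1, since either could move the positive limb the same way. That list had a median of 0.131 with members going both ways, and nothing is drawn from it. Loss of BMAL1 in neutrophils stays open and untested without an unfloxed control, and Arntl itself was not lower. The Cre in the labels is active in neutrophils. Loss of BMAL1 in the cells that bring endothelial RNA is therefore not what the labels describe, and it was not tested.

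Core neutrophil genes were higher as a list in the Bmal1-labelled libraries, with positive log2 differences for all 16 members. Group means did not all follow. S100a8 averaged 893.4 against 1152 in the Cxcr4-labelled group, S100a9 2474 against 2954, Retnlg 246.8 against 350.8 and Lcn2 216.8 against 392.9. Each of these was highest in Cxcr4-labelled library 1. The low neutrophil content of Cxcr4-labelled library 3 may account for much of it, since the median difference of the core neutrophil list was 1.44 with that library and 0.326 without it. The median log2 ratio to the Bmal1-labelled mean was -4.08 in Cxcr4-labelled library 3. It was also below 0 in libraries 1 (-0.358) and 2 (-0.819). The SD over core neutrophil genes of the log2 ratio to the Bmal1-labelled mean was 1.29, 1.18 and 1.15 in Cxcr4-labelled libraries 1, 2 and 3. Between the 2 Bmal1-labelled libraries it was 0.337, so the list did not shift by a single factor. Counting error was not separated from this spread. How far the neutrophil RNA differs in kind, and whether either genotype has an effect, stays open without a control.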
